A study of Oncorhynchus mykiss with 15 samples.

How the data were processed

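Small RNA libraries came from liver of rainbow trout (Oncorhynchus mykiss), extracted with Trizol per the labels' protocols, in 5 groups of 3 libraries taken from the sample labels. The deposited table gives one value per row and library, used here as a score: a value that was normalized to a scale not given in the sources used here and rounded to whole numbers. It is called TPM in its name, but column totals over all rows run from 3708956 to 11531840, so the values were not scaled to a common total, and they are not raw counts. The comparisons had been set out for raw counts in case these were given, but the unit is a score, so limma was used. The authors also deposited 1 p-value per row, from a test that is not named; among the authors' values, 230 of 1213 rows have a p-value under 0.05, and this column was not used further. Aligner, miRNA annotation, genome build and filters are not given in the sources used here. Row names join a species prefix, a miRNA name and end or base changes, or mark a predicted candidate with PC (259 rows); a species prefix is the entry matched, not the organism of the sample. No genome was used, so no coordinates are given, and forms of a miRNA that differ by a base or an end can share reads. Sequences are printed for salmon-named (ssa) rows only.

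Rows with a mean of at least 10 over the 15 libraries were tested (752 rows, 634 sequences). Values were transformed as log2(value + 1), a scale that understates changes of low rows, and fitted with limma 3.58.1 in R 4.3.3, with a trended variance and all 5 groups in 1 fit. p-values were adjusted by Benjamini-Hochberg within each comparison, at a threshold of 0.05. Fold changes are on the log2(value + 1) scale. Each hypoxia duration and reoxygenation were compared with control, reoxygenation with 24 h of hypoxia, and the 5 groups and 3 durations by moderated F-tests. The miR-92a row had an exact two-sided permutation test. The 11 miRNA lists (hypoxia-responsive, miR-17-92 family clusters, hepatocyte, let-7, metabolic, red blood cell, white blood cell and inflammation, endothelial and stromal, epithelial and bile duct, muscle, neural and endocrine) were tested with camera at a preset correlation of 0.01 and with an estimated one. Lists match by miRNA number, and some miRNAs are on more than 1 list.

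Before the data were examined, the groups, tests, lists, naming rule and a first set of other settings were fixed. Named were, per comparison, the 10 largest rises and 10 largest falls among rows past the threshold whose groups did not overlap and whose higher group mean was at least 50. Where fewer than 5 rows passed, the 5 smallest unadjusted p were named as not passing. F-tests gave their 10 smallest p. Always named were the rows of miR-92, miR-210, miR-122, miR-462 and miR-731 (the main forms singly and all 28 profiles by range), the 2 most abundant members of each list (the rule allowed 2 to 4) and the 10 most abundant rows. Members of lists named because they passed, profiles named under the GC correction and the arms of a miRNA were chosen after their values were seen. Rows with identical values were named once.

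Other settings tried were other pseudocounts, filters, scalings, variance models, sums over forms, a replicate block, fits on the compared groups alone and each library left out. Forms were summed where their names gave the same number, letter and arm, or the same number and letter and no arm. Added after seeing the data were 1 row per profile, scaling to the library total with and without miR-122, a per-library GC correction (lowess, span 0.5) and a fit without library 1 of 24 h hypoxia and library 1 of reoxygenation. The fit was tested on simulated data for 12 h hypoxia against control, with 200 of 752 rows changed. It called 9.2% of rows changed by 1 on the log2 scale, 49.2% of those changed by 2, 73.4% of those changed by 3 and 81% of those changed by 4, and 4.20% of calls were false. The simulated noise was normal, independent between rows, equal in all libraries and without a floor at 0, so these shares hold for such data only.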

Results

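MicroRNA levels were measured by small RNA sequencing in the liver of rainbow trout in 5 groups of 3 libraries: control fish, fish after 3, 12 or 24 h of hypoxia, and fish after 3 h of reoxygenation. The deposited table listed 1213 rows, which held 1019 distinct sets of values, because rows with different names can carry the same measurement. Of these rows, 752 (622 distinct profiles, a profile being one set of values over the 15 libraries) had a mean of at least 10 and were tested. The values were normalized and rounded, so the number of reads behind each one is unknown and no counting interval can be given. Column totals over distinct profiles ran from 2090585 in control library 3 to 6181106 in library 1 of 24 h hypoxia. Nothing in the labels says more about the replicates than that they are separate samples, so the p-values measure the spread between these samples.

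The liver profile was dominated by miR-122, the most abundant miRNA of hepatocytes. The row ssa-miR-122-5p_R-1 (TGGAGTGTGACAATGGTGTTT) made up 40.4% ± 14.5 of the library total (SD, n = 15). It was followed by ssa-miR-21b-5p at 8.34% ± 2.67, ssa-miR-22a-3p at 6.87% ± 2.26, ssa-miR-100a-5p_R-1 at 5.98% ± 2.02 and ssa-miR-30b-5p_R-1 at 3.37% ± 1.62. The next 5 were ssa-miR-462a-5p, ssa-miR-146a-5p, ssa-let-7e-5p, ssa-let-7a-5p and ssa-miR-143-3p_R+1, at 2.55%, 2.48%, 1.54%, 1.53% and 1.36%. All miR-122 rows together took 21.5% to 35.7% of the total in the 6 control and 3 h hypoxia libraries and 55.7% to 60.2% in the 3 libraries of 12 h hypoxia. The share was 59.0% in library 1 of 24 h hypoxia against 35.7% and 25.2% in the other 2, and 57.2%, 26.5% and 52.9% in the reoxygenation libraries. Library 1 of reoxygenation also stood apart, with an SD of log2 differences of 2.87 and 2.91 to the other 2 libraries of its group, which differed from each other by 1.42. To a lesser degree so did library 1 of 24 h hypoxia (2.15 and 2.05, against 1.33) and control library 1 (1.83 and 1.72, against 1.06). Control library 1 enters every comparison with control.

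**Figure D1:**
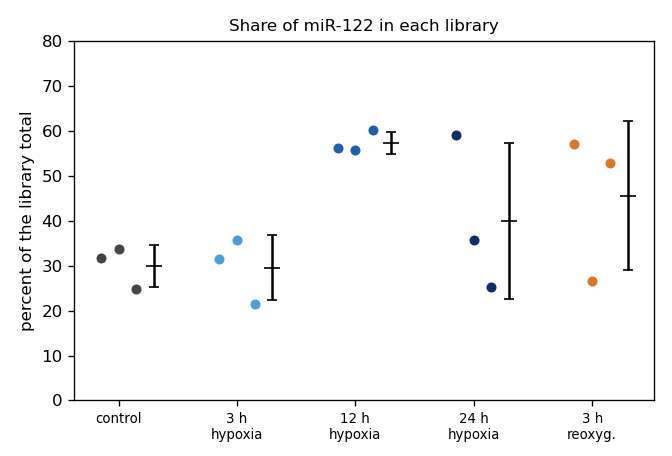
Percent of each library's total taken by all miR-122 rows (y axis) in the 5 groups (x axis); points are the 3 libraries of a group and the bar is the mean with its SD. The 3 libraries of 12 h hypoxia lie between 55.7% and 60.2%, above the 21.5% to 35.7% of control and 3 h hypoxia.

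The row sha-miR-92a_L+2R+4, a longer form of miR-92a that the study singled out for functional work, was at 72.7 ± 8.39 in control (SD, n = 3), 97.3 ± 57.8 after 3 h of hypoxia, 28.7 ± 7.77 after 12 h, 26.0 ± 12.2 after 24 h and 17.7 ± 6.35 after reoxygenation. All 3 libraries lay below all 3 controls at 12 h, at 24 h and after reoxygenation, with log2 changes of -1.34, -1.53 and -2.02. Groups did not overlap, in either direction, in 40.7%, 15.7% and 16.2% of all rows in these comparisons, where chance gives 10%. None of the changes of this row passed: the exact two-sided permutation p was 0.1 in each of these 3 comparisons (0.133 adjusted over the 4 comparisons), the smallest that 3 against 3 can give, and 0.7 at 3 h. In limma with Benjamini-Hochberg adjustment over all rows, adjusted p was 0.995 at 3 h, 0.152 at 12 h, 0.214 at 24 h and 0.0871 after reoxygenation. With the other miR-92a rows whose names give no arm added to this row, the direction changed at 3 h and at 24 h, as given below. That sum left out ssa-miR-92a-3p. It held ola-miR-92a_R+2_2, which averaged 1441 over all libraries, against 48.5 for sha-miR-92a_L+2R+4. The main mature form, ssa-miR-92a-3p, averaged 20910 ± 1603 in control and 14582 ± 365 at 12 h (limma adjusted p = 0.247), and ssa-miR-92b-3p 20225 ± 6072 and 8347 ± 2451 (limma adjusted p = 0.0782).

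**Figure D2:**
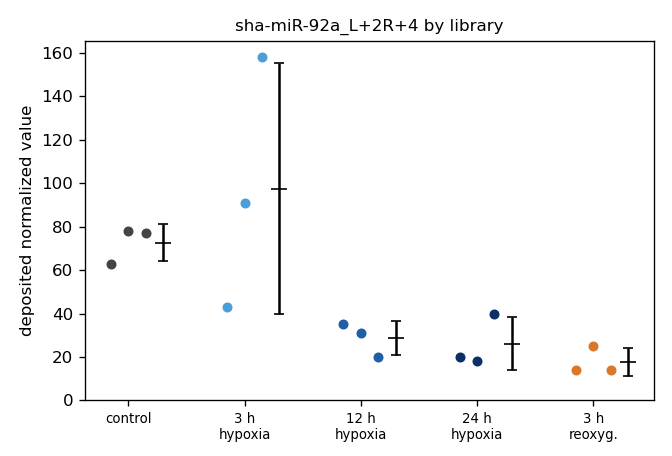
Deposited normalized value of sha-miR-92a_L+2R+4 (y axis) in the 5 groups (x axis); points are single libraries and the bar is the mean of 3 with its SD. The means are 72.7, 97.3, 28.7, 26.0 and 17.7 from left to right, and no difference from control passed the test.

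No row of miR-92, miR-210, miR-122, miR-462 or miR-731, all fixed for naming, passed against control in any group with the settings used here and adjustment over all tested rows. ssa-miR-210-3p, a miRNA widely induced by hypoxia in vertebrates, averaged 2026 ± 875 in control, 1912 ± 987 at 3 h, 1230 ± 245 at 12 h, 1067 ± 64.1 at 24 h and 1553 ± 825 after reoxygenation. Of the teleost cluster of miR-462 and miR-731, ssa-miR-462a-5p averaged 78398 ± 49567 in control and 71035 ± 22674 at 12 h, and ssa-miR-731-5p 24751 ± 8517 and 12734 ± 2922, with limma adjusted p of 0.983 and 0.337. ssa-miR-122-5p_R-1 averaged 911090 ± 442245 in control and 3296174 ± 146089 at 12 h, a log2 difference of 1.97 ± 0.61 (SE) that missed the threshold (limma adjusted p = 0.0645). Over all 28 profiles of these miRNAs, log2 differences at 12 h on the deposited scale ran from -3.70 to -0.10 for 8 of miR-92, from -2.95 to 1.01 for 5 of miR-210, from 0.33 to 1.97 for 5 of miR-122, from -3.37 to -0.02 for 5 of miR-462 and from -3.59 to -0.44 for 5 of miR-731. The smallest limma adjusted p among them was 0.0592, for ssa-miR-92a-4-5p_R-1, so no direction is drawn for the levels of these families. That row passed at 12 h in 8 of 21 other settings, ssa-miR-92a-5p_R-1_1ss9AC in 5 of 21 and ssa-miR-92b-3p in 5 of 22. ssa-miR-122-5p_R-1 and ola-miR-92b_2ss10TC23CT each passed in 4 of 22, ssa-miR-462a-3p in 3 of 22 and ola-miR-731_L+1R+5 in 2 of 21. ssa-miR-92a-3p passed in 1 of 22, and ssa-miR-462b-3p, mdo-miR-210-3p_L-1R+3 and ola-miR-210-3p_L-1R+5 in 1 of 21 each. With the GC correction ssa-miR-92a-3p and ssa-miR-92b-3p were above control, at 0.29 and 0.33, and others of the 28 also changed sign, as given below.

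After 3 h of hypoxia no miRNA was called different from control. The rows with the smallest unadjusted p, none of which passed, were ssa-miR-106a-3p_R-1 (10.3 ± 7.57 in control and 0.667 ± 1.15 at 3 h), ssa-miR-101a-3p (429 ± 299 and 164 ± 31.8) and the predicted candidates PC-3p-11974_177, PC-5p-2138_1889 and PC-3p-3375_979. limma called 0 of 752 rows, with 13 at an unadjusted p under 0.05, and the smallest adjusted p was 0.995. Scaled to the library total, the median row changed by 0.20 in place of -0.01, and still 0 were called (6 at an unadjusted p under 0.05 in limma). Libraries of the groups did not overlap in 5.85% of rows, where chance gives 10%. By camera over rows with a preset correlation, red blood cell miRNAs (median log2 change 0.47 over 35 profiles) and white blood cell and inflammation miRNAs (0.47 over 40) stood above the other miRNAs, with adjusted p of 0.000124 and 0.0295, and of 0.00320 and 0.0478 with each profile counted once. Epithelial and bile duct miRNAs stood below them (-0.61 over 13, adjusted p = 0.0213, and 0.0287 over profiles). All 3 calls were lost at adjusted p = 0.725 with an estimated correlation.

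After 12 h of hypoxia miR-19 and miR-101 family members were among the miRNAs that rose. ssa-miR-19a-3p_R+1 (TGTGCAAATCTATGCAAAACTGT), of the miR-17-92 family of clusters, went from 14 ± 12.2 in control to 331 ± 57.1 (SD, n = 3), 26.9-fold, and ssa-miR-19c-3p from 43.7 ± 8.33 to 563 ± 9.71, 12.8-fold. ssa-miR-101b-3p_R+1 (TACAGTACTATGATAACTGAAG) went from 526 ± 264 to 6126 ± 1553, 12.5-fold, and ssa-miR-101a-3p from 429 ± 299 to 2181 ± 227. ssa-miR-152-3p, of the miR-148/152 family, rose from 10243 ± 8284 to 61191 ± 5397, and ssa-miR-126-3p, known from endothelial cells, from 9523 ± 7019 to 41255 ± 4217. The strongest falls were in low rows: cfa-miR-486_R+1 and aca-miR-193-5p_R+1 were listed at 0 in all 3 libraries, against 197 ± 76.6 and 70.7 ± 30.6 in control. Both were also listed at 0 in all 3 libraries of 24 h hypoxia. In reoxygenation library 1, which may hold reads from a mammalian sample, the first was at 65 and the second at 449. Both were listed at 0 in the other 2 libraries of that group. Whether mammalian reads account for part of the values of these rows was not tested. At 12 h the fall of cfa-miR-486_R+1 stayed past the threshold in 22 of 22 other settings, and that of aca-miR-193-5p_R+1 in 10 of 21.

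**Figure D3:**
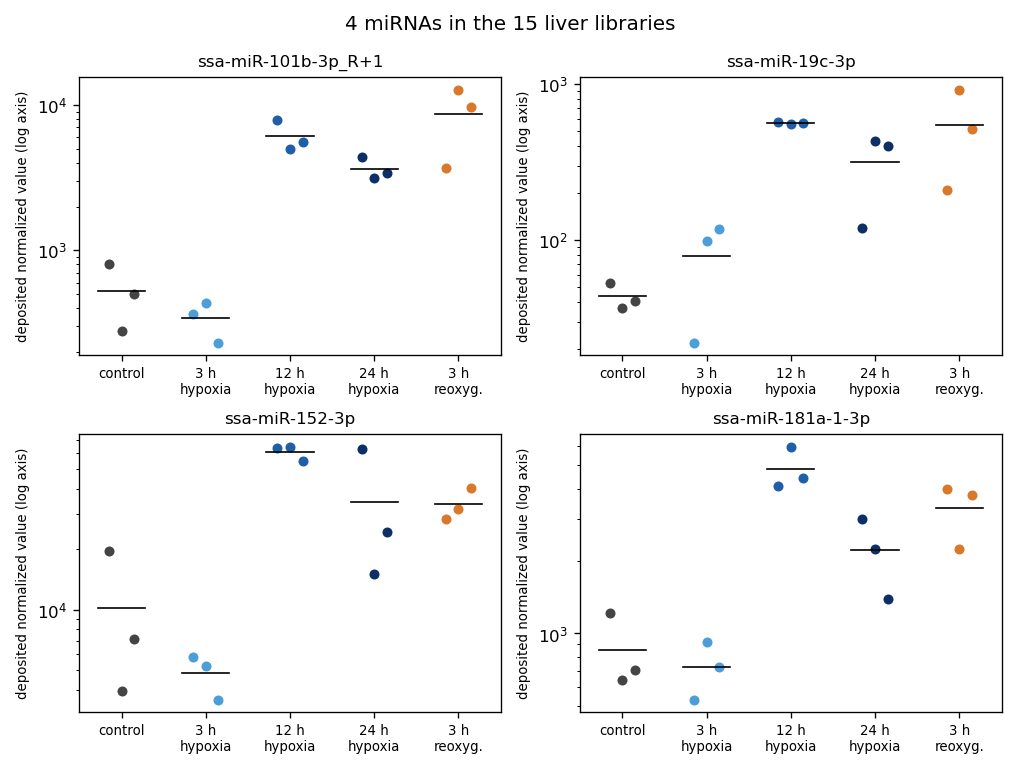
Deposited normalized values (y axes, log scale) of ssa-miR-101b-3p_R+1, ssa-miR-19c-3p, ssa-miR-152-3p and ssa-miR-181a-1-3p in the 5 groups (x axes); points are single libraries and lines are means of 3. For ssa-miR-101b-3p_R+1 the means are 526 in control, 343 at 3 h, 6126 at 12 h, 3648 at 24 h and 8708 after reoxygenation.

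limma called 54 of 752 rows at 12 h, 39 higher and 15 lower, which are 44 distinct profiles, 30 higher and 14 lower. The log2 changes of ssa-miR-101b-3p_R+1, ssa-miR-19c-3p and ssa-miR-152-3p were 3.64 ± 0.48 (SE), 3.67 ± 0.67 and 2.89 ± 0.54, with limma adjusted p of 0.00124, 0.00942 and 0.00942. The other named rows that rose were ssa-miR-19a-3p (4.61), ssa-miR-7132a-3p_R-1 (4.66), ssa-miR-181a-1-3p (2.54) and aca-miR-15a-5p_R+2_1ss10AG (2.29). ssa-miR-7132a-3p_R-1 was near the floor in control, at 0, 0 and 10. Its call held in 13 of 21 other settings and was lost with the GC correction and with both scalings to the library total. Named rows that fell were ola-miR-199a-5p_R+1_1ss18CG (-4.92), ssa-miR-125a-3p (-4.29), cpi-let-7g-3p_1ss8GA (-2.85), ssa-let-7h-3p_1ss4TG (-1.74), hsa-miR-4454_L-2_1ss8AG (-2.40) and 3 miR-9226 rows (-3.09, -2.58 and -1.98). The median row changed by -0.20. With values scaled to the library total the median was -1.12 and the split was 7 higher and 67 lower of 74 called. It was 8 and 12 with miR-122 left out of that total, and 42 and 8 with quantile normalization.

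The called rows at 12 h followed base composition: median GC content was 37.5% for the profiles that rose and 61.1% for those that fell. A per-library GC correction left 13 rows called and 10 of the 44 profiles, among them ssa-miR-101b-3p_R+1 (2.24 ± 0.41, limma adjusted p = 0.0268), ssa-miR-19c-3p, ssa-miR-152-3p, ssa-miR-181a-1-3p, ssa-miR-140-5p and ola-miR-199a-5p_R+1_1ss18CG. The 34 lost profiles had a median absolute log2 change of 2.32 before and 1.47 after it, with median SE of 0.56 and 0.52. They included ssa-miR-101a-3p and both ssa-miR-19a-3p rows, each at limma adjusted p = 0.0688. The log2 change went from 2.56 to 1.57 for ssa-miR-101a-3p, from 4.75 to 3.65 for ssa-miR-19a-3p_R+1 and from 4.61 to 3.63 for ssa-miR-19a-3p, so the last 2 stayed large. Named falls were lost too: ssa-miR-125a-3p became -2.69, hsa-miR-4454_L-2_1ss8AG -0.65 and the 3 miR-9226 rows -1.27, -0.98 and -0.41. Their limma adjusted p were 0.174, 0.553, 0.388, 0.279 and 0.666. aca-miR-193-5p_R+1 and cpi-let-7g-3p_1ss8GA were also lost. The falls of cfa-miR-486_R+1, ola-miR-199a-5p_R+1_1ss18CG and ssa-let-7h-3p_1ss4TG stayed past the threshold. Leaving out 1 library moved the count to 109, 4 and 28 without control libraries 1, 2 and 3, and to 9, 18 and 23 without libraries 1, 2 and 3 of 12 h hypoxia.

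The most abundant members of the fixed lists mostly missed the threshold at 12 h. Of the 2 most abundant members of each list, ssa-let-7e-5p (log2 change 1.97 ± 0.54, SE, limma adjusted p = 0.0402) and ssa-miR-499b-5p_R-1 of muscle (2.18 ± 0.45, limma adjusted p = 0.0120) rose. With the GC correction these became 0.57 and 0.95, with limma adjusted p of 0.553 and 0.279. Differences that did not pass were 0.41 for ssa-miR-21b-5p, on the hypoxia-responsive and inflammation lists, 1.05 for ssa-miR-22a-3p of hepatocytes, 0.25 for ssa-let-7a-5p, and 0.78 and 0.05 for ssa-miR-26a-5p and tni-miR-27c of the metabolic list. The red blood cell miRNAs ssa-miR-16a-5p and gmo-miR-16b-5p_R-1_1ss17TC differed by 1.10 and 1.74, ssa-miR-146a-5p of inflammation by -1.03, and ssa-miR-143-3p_R+1 and ssa-miR-199a-5p of stroma by 0.46 and -0.90, none past the threshold. Nor did ssa-miR-200b-3p_R-1 and ssa-miR-200a-3p_R-1 of epithelia (-0.84 and -0.43), ssa-miR-133b-3p_L-1R+2 of muscle (-1.06), or ssa-miR-128-3p and ssa-miR-7a-5p of the neural and endocrine list (0.90 and 0.75) pass. Scaled to the library total, the differences of ssa-miR-21b-5p, ssa-let-7a-5p, ssa-miR-26a-5p, tni-miR-27c, ssa-miR-143-3p_R+1, ssa-miR-128-3p and ssa-miR-7a-5p were below 0.

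Over all 622 tested profiles, 30 rose and 14 fell at 12 h. By the fixed lists, 4 of 38 profiles of the miR-17-92 family clusters rose at 12 h, all of them forms of miR-19a-3p or miR-19c-3p. In this list 0 fell over all rows, and adjusted over the list alone 4 rose and 4 fell. Of 57 hepatocyte profiles 2 rose, miR-101a and miR-101b (2 adjusted over the list alone), and of 32 let-7 profiles 2 rose, ssa-let-7e-5p and ssa-let-7g-5p, and 2 fell, both 3p forms (3 and 7 adjusted over the list alone). ssa-let-7e-5p went from 33934 ± 20561 to 119509 ± 7220. Red blood cell miRNAs had 2 of 35 higher, both miR-15a forms, and 1 lower, the miR-486 row (5 and 1 adjusted over the list alone). Whether mammalian reads account for part of the values of the miR-486 row was not tested. In the endothelial and stromal list 2 of 39 were higher, both arms of miR-126, and 1 was lower, a miR-199a form (2 and 1 adjusted over the list alone). White blood cell and inflammation miRNAs had 1 of 40 higher, ssa-miR-181a-1-3p (1 adjusted over the list alone), and muscle miRNAs 1 of 3, ssa-miR-499b-5p_R-1 (1 adjusted over the list alone). Metabolic miRNAs had ssa-miR-29b-3p higher and ssa-miR-33a-3p lower among 39 (0 and 1 adjusted over the list alone), and hypoxia-responsive miRNAs had 1 of 43 lower, the same miR-199a form (1 adjusted over the list alone). None of 13 epithelial and bile duct and none of 8 neural and endocrine profiles passed, also when adjusted over the list alone. Of these members, ssa-let-7g-5p (0.13, limma adjusted p = 0.896 after GC correction), ssa-let-7e-5p, cpi-let-7g-3p_1ss8GA, ssa-miR-29b-3p, ssa-miR-499b-5p_R-1, ssa-miR-101a-3p, both miR-126 arms, both miR-15a forms and the miR-19 forms other than ssa-miR-19c-3p were not past the threshold with the GC correction. These miR-19 forms kept much of their change: 3.65 for ssa-miR-19a-3p_R+1, 3.63 for ssa-miR-19a-3p and 4.16 for dre-miR-19c-3p_R-1, against 4.75, 4.61 and 4.79 before it. No list was called by camera at 12 h or at 24 h, where the smallest adjusted p were 0.0800 and 0.602.

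After 24 h of hypoxia ssa-miR-101b-3p_R+1 was at 3648 ± 650 against 526 ± 264 in control, 7.50-fold, and ssa-miR-25-3p (CATTGCACTTGTCTCGGTCTGA), of the same family as miR-92, at 5602 ± 1014 against 2250 ± 335, 2.48-fold. mmu-miR-5099_L+2R-1 averaged 96.0 ± 53.7 and was listed at 0 in all controls, and cfa-miR-486_R+1 was listed at 0 in all 3 libraries. limma called 5 rows, 4 higher and 1 lower, with 100 at an unadjusted p under 0.05. The fifth row, named after its value was seen, was the predicted candidate PC-3p-13989_144, at 19.3 and listed at 0 in controls. The log2 changes of ssa-miR-101b-3p_R+1 and ssa-miR-25-3p were 2.91 ± 0.48 (SE) and 1.31 ± 0.27, with limma adjusted p of 0.00833 and 0.0325. The call of ssa-miR-25-3p held in 12 of 22 other settings, and scaled to the library total its change was 0.90 (limma adjusted p = 0.315). The median row changed by -0.16. Scaled to the library total it changed by -0.52, and 8 rows were called, 2 higher and 6 lower. The count was 30 without control library 1, 0 without control library 2 or 3 (89 and 75 at an unadjusted p under 0.05 in limma), 12 without library 1 of 24 h hypoxia and 3 without library 2.

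After 3 h of reoxygenation the same miR-101b-3p and miR-19 forms stood above control. ssa-miR-101b-3p_R+1 was at 8708 ± 4589, 16.0-fold, ssa-miR-19a-3p at 244 ± 214 against 6 ± 4.58 and ssa-miR-19c-3p at 546 ± 355 against 43.7 ± 8.33. ssa-miR-15a-5p_L-2_1ss18GA rose from 2315 ± 660 to 11068 ± 814, 4.92-fold, and ssa-miR-25-3p from 2250 ± 335 to 5481 ± 641, 2.44-fold. ola-miR-199a-5p_R+1_1ss18CG fell from 128 ± 41.5 to 2.00 ± 3.46 and cpi-let-7g-3p_1ss8GA from 756 ± 223 to 165 ± 76.8. With all forms of miR-199a-5p summed the log2 changes were -0.90 at 12 h and -0.82 after reoxygenation, with limma adjusted p of 0.211 and 0.407. limma called 16 rows, 11 higher and 5 lower, or 15 profiles. ssa-miR-101b-3p_R+1 had the smallest limma adjusted p, 0.000394, at a log2 change of 4.00 ± 0.48 (SE). ssa-miR-19a-3p_R+1, ssa-miR-101a-3p, ssa-miR-181a-1-3p and bta-miR-2478_L-2 also rose, and cfa-miR-486_R+1 and pal-miR-9226-5p_1ss4AG fell. cfa-miR-486_R+1 was at 65 in reoxygenation library 1 and listed at 0 in the other 2, and its call held in 13 of 22 other settings. The call of pal-miR-9226-5p_1ss4AG was lost with forms summed (-1.07 in place of -4.36, limma adjusted p = 0.382). Hypoxia-responsive miRNAs stood below the others by camera over rows (median -0.50, adjusted p = 0.0232), a call that was lost over the 43 distinct profiles (adjusted p = 0.0776) and with an estimated correlation (adjusted p = 0.746). The median row changed by -0.11. Scaled to the library total it changed by -0.48, and the split was 5 higher and 6 lower. In reoxygenation library 1, profiles named after mammals stood a median of 2.40 (log2) above the other 2 libraries, and salmon-named profiles 0.0056. Fitted on the 2 groups alone limma called 0 rows (62 at an unadjusted p under 0.05), and the count was 6 without control library 2, 56 without reoxygenation library 1 and 4 without library 3.

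Profiles called in the same direction at 12 h and after reoxygenation numbered 8 higher and 4 lower, where independent lists would share 0.531 and 0.0900. Unchanged groups simulated against shared controls shared 0.01 on average and at most 1, but such groups give few calls at all, so this says little about the shared controls. The covariance of the log2 changes was 1.72, against 0.509 in that simulation. Part of the overlap may still come from the shared controls, which were too few to split.

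Against 24 h of hypoxia, 3 h of reoxygenation gave no called miRNA. Smallest in p, and not past the test, were PC-5p-10831_202 (36.3 ± 21.7, listed at 0 at 24 h), 3 forms of miR-7550, of which gmo-miR-7550-5p_L-1R+2_1 averaged 386 ± 391 at 24 h and 66.7 ± 49.2 after reoxygenation, and mmu-mir-6240-p3_1ss2TG. limma called 0 rows, with 28 at an unadjusted p under 0.05, and 5.05% of rows did not overlap, where chance gives 10%. The labels do not give the length of hypoxia before reoxygenation. By camera, hypoxia-responsive miRNAs were lower (median -0.36, adjusted p = 0.00113, and 0.00289 over profiles) and red blood cell miRNAs higher (0.57, adjusted p = 0.000528, and 0.00197 over profiles), both lost at adjusted p = 0.434 with an estimated correlation.

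The 3 durations of hypoxia differed most in the same miRNAs. ssa-miR-101b-3p_R+1 averaged 343 ± 104 at 3 h, 6126 ± 1553 at 12 h and 3648 ± 650 at 24 h. ssa-miR-152-3p was at 4861 ± 1158 at 3 h and 61191 ± 5397 at 12 h, and ssa-miR-101a-3p at 164 ± 31.8 and 2181 ± 227. The moderated F-test of limma called 85 rows (70 profiles), led by ssa-miR-101b-3p_R+1 (adjusted p = 0.000462) and ssa-miR-101a-3p (0.000772). Next came cfa-miR-486_R+1, ssa-miR-181a-1-3p, ssa-miR-152-3p, cpi-let-7g-3p_1ss8GA, ssa-miR-106a-3p_R-1, ssa-miR-499b-5p_R-1, mmu-miR-5099_L+2R-1 and ola-miR-199a-5p_R+1_1ss18CG. The GC correction left 31 rows. Without libraries 1, 2 and 3 of 3 h hypoxia the count was 31, 17 and 7, without those of 12 h hypoxia 11, 24 and 17, and without libraries 1 and 3 of 24 h hypoxia 150 and 52.

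Over all 5 groups 48 rows (42 profiles) differed by limma's F-test, with ssa-miR-101b-3p_R+1 first (adjusted p = 7.35e-05), then ssa-miR-101a-3p, cfa-miR-486_R+1 and ssa-miR-181a-1-3p. cpi-let-7g-3p_1ss8GA, ola-miR-199a-5p_R+1_1ss18CG, ssa-miR-152-3p, PC-3p-13989_144, ssa-miR-15a-5p_L-2_1ss18GA and mmu-miR-5099_L+2R-1 completed the 10 smallest p. Single libraries moved this count too: it was 85 and 22 without control libraries 1 and 2, 25 and 19 without libraries 2 and 3 of 3 h hypoxia, and 18, 24 and 19 without libraries 1, 2 and 3 of 12 h hypoxia. It was 84 without library 1 of 24 h hypoxia, and 98 and 26 without reoxygenation libraries 1 and 3.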

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

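The tests of other splits, base composition, length, miR-122 and mammal-specific miRNAs were written down before the values they measure were computed; the test on miR-462 and miR-731 was chosen after their 12 h values were seen. The division into early and later groups was itself chosen after the data were seen, so its count is no finding of its own. The change from control differed between 12 h and 3 h of hypoxia in 126 rows (65 higher and 61 lower at 12 h), and between 24 h and 3 h in 37 rows (22 higher and 15 lower), each by limma's test of the difference. The first of these counts was 242 (17 higher and 225 lower) with scaling to the library total, 139 (37 and 102) with miR-122 left out of it, 107 (70 and 37) with quantile normalization, 80 (45 and 35) with forms summed and 64 (28 and 36) with a GC correction. The second was 38 (8 higher and 30 lower), 25 (8 and 17), 38 (25 and 13), 16 (12 and 4) and 45 (28 and 17) in the same order, and 15 with no minimum mean and 22 without the variance trend. Without library 1 of 24 h hypoxia and library 1 of reoxygenation the counts were 233 (95 and 138) and 84 (29 and 55). Between 24 h and 12 h limma called 0 rows, with 128 at an unadjusted p under 0.05, and 97 without those 2 libraries. ssa-miR-101b-3p_R+1 (log2 difference 4.17 between 12 h and 3 h), ssa-miR-101a-3p (3.74), ssa-miR-152-3p (3.68) and ssa-let-7e-5p (2.66) were higher at 12 h, and ssa-let-7h-3p_1ss4TG (-2.05) and ssa-miR-33a-3p (-1.99) lower.

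Control and 3 h hypoxia parted from the 3 later groups in 138 of 622 profiles, 67 higher and 71 lower later. The difference followed GC content (Spearman rho -0.367), with a median GC of 40.9% for the higher and 52.4% for the lower profiles. A GC correction still left 137 called (ratio 0.993), with 97 of the 138 among them. A length correction gave a ratio of 1.08 and kept 132 of the 138. Dividing by the library total without miR-122 gave a ratio of 1.12 and kept 124. The values before it were not divided by a total here, so this adds a scaling and does not only take miR-122 out. So none of these, as corrected for here, accounts for the whole pattern, though base composition and the share of miR-122 stay open as parts of it. Mammal-specific miRNAs were 1.41% of the profiles that were lower later. The criterion written beforehand set this share against one above 50%, and it was wrong, since the 11 such profiles tested could make up no more than 15.5% of the 71 lower ones, so reads from mammals stay open for these. For the 67 higher ones, fewer such reads would raise all trout sequences alike. The 10 teleost-only profiles of miR-462 and miR-731 were not raised, with a median difference of -1.19 ± 1.01 (SD), against 1.79 for the higher profiles. This comparison cannot exclude reads from mammals. The 67 were selected for being higher, and the 10 are on the hypoxia-responsive list and were chosen after their 12 h values were seen. At 12 h alone, where the 3 libraries had Spearman correlations with GC content across profiles of -0.50, -0.49 and -0.60, the GC correction left 13 of 54 rows, so base composition may account for part of the 12 h calls. Dividing by the total without miR-122 left 20 rows at 12 h, with 17 of the 44 profiles. The share of miR-122 therefore stays open for part of the 12 h calls too. Duration of hypoxia stays open beside a batch, which the labels do not give.

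For the comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. The real split and the highest other split gave 0 and 1 rows at 3 h, 54 and 0 at 12 h, 5 and 24 at 24 h, 16 and 2 for reoxygenation against control, and 0 and 16 for reoxygenation against 24 h. As many rows as in the real split came in 10, 1, 2, 1 and 10 of these 10 splits. At 24 h 1 other split called 24 rows, against 5 in the real one. Whether a structure of the samples other than their groups lies behind this was not tested. Over 100 drawn splits, the F-test gave as many rows in 1, the real one, for the 5 groups (48, highest other 47) and in 1 for the 3 durations (85, highest other 45). Both shares lie under 0.05 with the settings used here, but for the 5 groups the highest other split came close to the real one.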

How the results depend on the processing

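The scalings to the library total, the GC correction, 1 row per profile and the fit without the 2 doubted libraries were chosen after the data were seen. None of the 37 named changes that passed reversed under any alternative run, and the counts for 3 h hypoxia against control and for reoxygenation against 24 h were 0 in all of them. At 12 h the count of 54 became 13 with the GC correction, 20 with scaling without miR-122, 121 with only the 2 groups fitted and 162 without library 1 of 24 h hypoxia and of reoxygenation, and ran from 4 to 109 with 1 library left out. The 24 h count of 5 became 10 with a pseudocount of 10, 2 with a minimum mean of 100, 3 with the robust trend, 8 with forms summed, with total scaling and with the GC correction, and 51 without those 2 libraries; it ran from 0 to 30 with 1 library left out. The reoxygenation count of 16 became 25 with quantile normalization, 0 with only the 2 groups and 76 without the 2 libraries, and ran from 4 to 56. Among the 3 durations, 85 became 56 with forms summed, 156 with only those groups, 157 with total scaling, 43 without miR-122, 31 with the GC correction and 245 without the 2 libraries, and ran from 7 to 150. Over the 5 groups, 48 became 26 with forms summed, 108 without the reoxygenation group, 28 with scaling without miR-122 and 183 without the 2 libraries, and ran from 18 to 98. Of 37 named changes, 22 kept the threshold and 15 lost it with the GC correction, as with only the 2 groups fitted. Those of ssa-miR-126-3p and pal-mir-9226-p5_1ss18CA at 12 h, ssa-miR-25-3p at 24 h and bta-miR-2478_L-2 after reoxygenation kept it in 12 of 22 other settings. Of 55 list tests 6 were called, 0 with an estimated correlation, 5 with each profile counted once and 3 without the 2 libraries, and from 4 to 11 with 1 library left out (11 without library 1 of 12 h hypoxia). Apart from fewer libraries or rows, the cause was not tested.

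Other miRNAs named at 12 h, none past the threshold before or after, changed sign, for a cause that was not tested. With scaling to the library total ssa-miR-21b-5p became -0.61, ssa-let-7a-5p -0.77, ssa-miR-26a-5p -0.24, tni-miR-27c -0.97, ssa-miR-143-3p_R+1 -0.56, ssa-miR-128-3p -0.12, ssa-miR-7a-5p -0.26, ssa-miR-210-5p -0.71, ccr-mir-210-p5_1ss17CT -0.00689, rno-miR-122-5p_L+1R-1 -0.24, fru-miR-122_L+2R-1 -0.69 and xla-mir-122-p3 -0.75. Without miR-122 in that total ssa-let-7a-5p became -0.0589, tni-miR-27c -0.25 and xla-mir-122-p3 -0.0027. With the GC correction ssa-miR-92a-3p became 0.29, ssa-miR-92b-3p 0.33, dre-miR-92a-3p_R+2 0.0157, ola-miR-92a_R+2_2 0.39, ssa-miR-210-3p 1.05, ola-miR-210-3p_L-1R+5 0.35, ssa-miR-122-2-3p_R-1 -0.11, fru-miR-122_L+2R-1 -0.44, xla-mir-122-p3 -0.65, ssa-let-7a-5p -0.74, tni-miR-27c -0.41 and ssa-miR-7a-5p -0.34. ssa-miR-21b-5p became -0.17 with quantile normalization, ssa-miR-462a-5p 0.0166 with median-of-ratios scaling and xla-mir-122-p3 -0.10 with a pseudocount of 10. With 1 library left out ssa-miR-462a-5p ran from -0.35 to 0.46, ssa-miR-462b-5p from -0.76 to 0.43, fru-miR-122_L+2R-1 from -0.18 to 0.64, xla-mir-122-p3 from -0.94 to 1.66, ola-miR-92a_R+2_2 from -0.51 to 0.48 and tni-miR-27c from -0.15 to 0.29. The miR-92a row of the study became -0.74 at 3 h and 0.19 at 24 h with forms summed, which adds only miR-92a rows whose names give no arm. It ran from -0.20 to 0.72 at 3 h with 1 library left out.

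Replicate numbers were not treated as pairs: 11 of 30 same-number pairs of libraries correlated above 0.1 (median 0.0222), and 4 of 15 libraries matched their own number best. A replicate block gave 70 rows at 12 h, 7 at 24 h, 19 after reoxygenation, 53 over the 5 groups and 110 over the 3 durations. Depth is unknown, so low rows have no stated precision.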

Other observations

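The balance between the 3p and 5p arms of a miRNA, which depends little on how libraries are scaled, also shifted. Each arm was the sum of all rows whose names gave the same number, letter and arm. Such a sum can join rows named after different precursors or species, so it is not the balance within a single precursor. Over 99 miRNAs with both arms above the minimum, limma called 22 at 12 h against control, 11 toward the 3p arm and 11 toward the 5p arm, 8 at 24 h and 15 after reoxygenation, and 0 at 3 h (2 at an unadjusted p under 0.05). At 12 h the 3p arm gained on the 5p arm by 4.95 ± 0.56 (log2, SE) for miR-19c (limma adjusted p = 5.33e-05), 4.05 ± 0.58 for miR-101b and 2.14 ± 0.51 for miR-152, and lost by -3.55 ± 0.64 for let-7g and -2.86 ± 0.50 for miR-140. Among the miRNAs fixed for naming it gained by 3.18 ± 0.93 for miR-92a (limma adjusted p = 0.0238) and lost by -2.66 ± 0.66 for miR-462a (limma adjusted p = 0.0120). The miR-92a shift came from a 5p sum near the floor, which joined rows of different precursor names. ssa-miR-92a-5p_R-1_1ss9AC was at 72, 24 and 52 in control and 0, 8 and 17 at 12 h. ssa-miR-92a-4-5p_R-1 was at 15, 50 and 26 in control and 0, 0 and 9 at 12 h. The level of ssa-miR-92a-3p itself was not raised at 12 h. After reoxygenation the shift was 4.52 ± 0.58 for miR-101b and 4.25 ± 0.56 for miR-19c, and -3.60 ± 1.13 for miR-462b (limma adjusted p = 0.0459). The 3p arm of miR-462b was near the floor: ssa-miR-462b-3p was at 57, 20 and 21 in control and 0, 14 and 0 after reoxygenation. The arms were chosen for a look after the data were seen, and arms differ in base composition.

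The tests on library 1 of reoxygenation and on mammal-specific miRNAs were written down before their values were computed. The level of miR-409 had been seen before the tests on mammal-specific miRNAs, and the high sum of the other mammal-specific miRNAs in library 1 before the test on names; the values by member of the epithelial list were looked up after its median was seen. Library 1 of reoxygenation differed from the other 2 by more than 4 (log2) upward in 77 of 622 profiles, 51 of them named after mammals, 10 from the mammal-specific lists and 4 named after salmon, and the difference did not follow base composition (Spearman rho 0.0391 across profiles). Profiles named after mammals, with list members left out, exceeded salmon-named ones by a median of 2.39, so reads from a mammalian sample may be in this library. Among other cell types, epithelial and bile duct miRNAs stood highest, with a median of 2.20 over 13 profiles, while neural and endocrine miRNAs stood at -1.55 and muscle miRNAs at -0.01. The most abundant epithelial members, ssa-miR-200b-3p_R-1 and ssa-miR-200a-3p_R-1, were at 8223 and 7215 in library 1 and averaged 2081 and 1931 in the other 2, and the salmon-named members had a median of 0.90 against 2.68 for the others. Liver itself holds bile duct cells, and miR-200 is shared with mammals, so for the epithelial miRNAs other cells of the sample stay open beside mammalian reads. Other trout cells would not account for the 11 mammal-specific profiles tested, which stood a median of 7.20 (log2) above the other 2 libraries. The labels set this library apart from its group in nothing.

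Mammal-specific miRNAs other than miR-409 summed to between 241 and 1296 in the 6 control and 3 h hypoxia libraries. In 7 of the 9 later libraries the sum was below all of these, and it was 839 in library 1 of 24 h hypoxia and 14860 in library 1 of reoxygenation, where bta-miR-320a alone was at 8997. The exact two-sided permutation p for the 6 against the 9 libraries was 0.0915, with a difference of 2.32 (log2). The criterion written beforehand counted a p above 0.05 as evidence against reads from mammals; it was a poor one, since a missed threshold does not show that the sums were alike and a single library carries the highest sum. Whether low amounts of mammalian reads, which could also differ by batch, follow the groups cannot be told apart from chance here.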
